A study of Homo sapiens with 9 samples.

How the data were processed

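ATAC-seq libraries were made from 3 sorted populations of regulatory T cells from the peripheral blood of 3 healthy donors. Per the labels, each donor gave 1 library of naive, 1 of memory and 1 of CD161+ Tregs, so the 9 libraries form 3 groups of 3 biological replicates, and the replicate number is the donor. Each library has 1 deposited list of called peaks. No pair of libraries held the same data: at most 0.00811% of the windows of a library had the same place and tag count in another library, over 36 pairs.

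Reads were aligned to hg19 with Bowtie2 2.2.9, per the submitters' processing notes, which also name HOMER and bedtools. Peaks were called with HOMER findPeaks in each library separately, with no control library and without pooling of donors, per the file headers. The headers give windows of 500 bp, a minimum distance of 50 bp between peaks, a false discovery rate of 0.001 and no limit on tags per position. Windows also had to hold 4 times the tag density of the surrounding 10000 bp, and at least 15 to 18 tags depending on the library. Whether reads were shifted for the Tn5 cut and whether duplicate reads were removed is not given in the sources used here. The highest position on chromosome 1 was 249201345, which lies inside hg19 and beyond the end of GRCh38, the assembly of the gene table that came with the data.

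The deposited normalized tag count of a window is a signal, the number of tags scaled by the authors to 10000000 tags per library, with mitochondrial tags in the total, per the file headers. The deposited findPeaks score is the unscaled tag number used for calling, and the deposited clonal fold change is a ratio of observed to expected tag positions. The score served only to rank the windows within a library, and the ratio was not used. Many windows overlapped each other in the deposited lists, so sums over windows exceeded the library total in most headers and were not used. Scaled values fell on steps smaller than 1 tag and could not be turned back into whole reads, so no count model was fitted.

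Windows of all libraries were merged into regions wherever they shared at least 1 bp. Windows of the Y chromosome, the mitochondrial genome and the XIST locus were left out. A region counted as called in a library if it held at least 1 of its windows. Its value was the normalized tag count of the highest window, on the log2 scale and centred on the library's median over the regions called in all 9 libraries. A relative tag count is the same value as a multiple of that median region. Shares of tags in called windows and of mitochondrial tags were summed over windows that did not overlap, so they are lower bounds. The total was 11248315 to 16179000 tags per library, and the p-values and intervals take no account of duplicated fragments. Differences between libraries in the share of tags in called windows limited what a missing call could show, since a region absent from a list can still be open.

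Tag counts of the 12163 regions called in all 9 libraries were compared with limma 3.58.1 (lmFit and eBayes with a trend, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, over all libraries in 1 fit. The fit without a donor term and the fit with donor as a block were both set before the data were examined. The replicate numbers pair the libraries because the same donor gave all 3 populations. Deviations of same-donor libraries from their group means correlated at 0.299 to 0.579 over all 9 such pairs (across regions, which are not independent replicates). The 2 fits differed by more than 1.5 times in every count, so both are given. On simulated data with 100 regions changed by 1 and 100 by 2 on the log2 scale among 12163, the fit without a block recovered 24% and 89% for memory against naive, 22% and 87% for CD161+ against memory, and 15% and 92% for CD161+ against naive. With the block, recovery was 53% and 97%, 55% and 90%, and 63% and 99%. False calls made up at most 0.877% of calls without and 5.66% with the block. The simulated comparisons differed only in the group changed and in the random draw, so their differences do not show unequal power. The simulated noise was normal and independent over regions, which the real data need not be. These shares may therefore not hold for the real data.

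Called and uncalled regions were compared as regions called in 3 of 3 libraries of one population and 0 of 3 of another. Similarity of libraries was the Jaccard index, the regions called in both over the regions called in either. Means were compared by exact permutation of the populations within donors, which has 36 distinct arrangements and a smallest p of 0.0278. Comparisons of 3 against 3 libraries have 10 splits and a smallest p of 0.10. Intervals of shares are exact Clopper-Pearson intervals at the 95% level and cover counting error only, with regions treated as independent.

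Alternatives were equally long lists (the 35090 windows with the highest findPeaks scores of each library), other merging rules (an overlap of 250 bp, a gap of up to 200 bp), a stricter threshold (for 3 of 3 against 0 of 3, each of the 3 calls above the library's median findPeaks score; for the number of called regions, a tag count of at least the pooled median), no centring, quantile normalization, summed windows, a filter on low values, a pseudocount of 1, a floor for uncalled values, only the 6 libraries compared, and leaving out each donor and each library. Equally long lists were equal in windows and were not set equal in regions. Regions were named by a rule fixed before the data were examined, with the nearest gene replaced by position where no gene names could be had in the files' build. For each comparison and direction these are the 3 largest log2 changes among regions past the threshold and changed the same way in all 3 donors, taken from each of the 2 fits. Added to them are 3 regions called in 3 of 3 against 0 of 3. The rule ranked these by gene, so a ranking outside it was used, the mean tag count relative to the median of each library's called regions. An hg19 annotation and sequence were not used here, so planned comparisons of gene lists, of positions relative to genes and of sequence motifs were not run, and the sort markers were not checked at their genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.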

Results

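Open chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts and tags accessible DNA, in 3 populations of human regulatory T cells (Tregs). From each of 3 healthy donors, CD25-high, CD127-low CD4 T cells were sorted into naive Tregs (CD45RA positive), memory Tregs (CD45RA and CD161 negative) and CD161+ Tregs (CD45RA negative). CD45RA is the long isoform of the phosphatase CD45 and marks naive T cells, and CD161 is a lectin-like receptor found on a part of memory T cells. The design asks how chromatin differs between naive and memory Tregs, and whether CD161+ Tregs stand apart from both.

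The libraries held 11248315 to 16179000 tags, and 40143 regions with a median width of 673 bp were called in at least 1 library. Of these, 12163 (30.3%) were called in all 9 libraries and 8499 (21.2%) in 1 library. All 3 donors shared 15887 regions in naive, 14011 in memory and 17540 in CD161+ Tregs. Naive libraries had 23714 ± 6229 called regions (SD, n = 3), memory libraries 20925 ± 6354 and CD161+ libraries 24781 ± 5193. The joint test of the 3 populations gave p = 0.306 (exact permutation within donors, two-sided). Memory libraries had fewer regions than naive libraries in each donor, with 27945 against 30557, 19260 against 22211 and 15569 against 18374. CD161+ libraries had fewer than naive libraries in donor 1 (27433) and more in donors 2 and 3 (28112 and 18797). The share of non-mitochondrial tags inside called windows was at least 19.2% ± 9.20 in naive, 18.5% ± 15.0 in memory and 25.9% ± 11.9 in CD161+ libraries (p = 0.556 by the same permutation test). In donor 2 this share was 8.89% in the memory and 33.2% in the CD161+ library, the widest gap between populations of a donor.

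**Figure D1:**
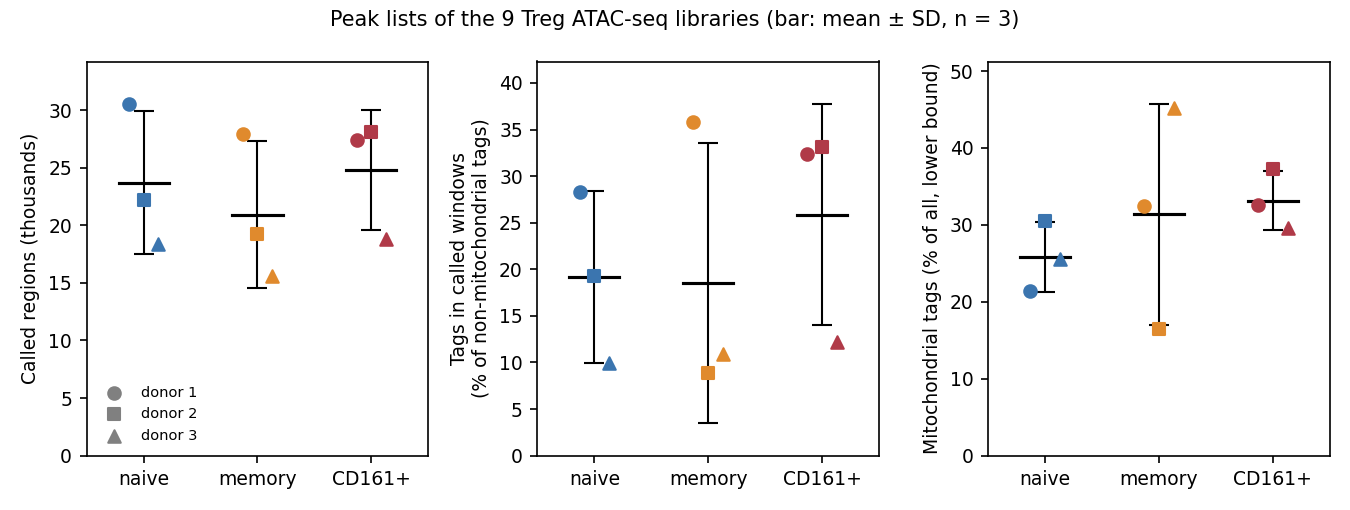
Called regions, share of non-mitochondrial tags in called windows and share of mitochondrial tags in the 9 libraries, by population on the x axis. Points are libraries with 1 symbol per donor, and bars give the mean and SD of n = 3. Donor 3 had the fewest called regions in each population, with 18374 in naive, 15569 in memory and 18797 in CD161+ Tregs.

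Memory Tregs were compared with naive Tregs first. The region at chromosome 9, 130158614 to 130159865 (hg19), was 4.40-fold higher in memory Tregs, with a relative tag count of 2.31 ± 0.426 (SD, n = 3) against 0.573 ± 0.324 in naive Tregs. Regions at chromosome 16, 75132215 to 75133106, and chromosome 12, 77458782 to 77460209, were 3.93-fold and 3.50-fold higher. In the other direction, the region at chromosome 8, 107281810 to 107284078, fell from 3.36 ± 0.640 in naive to 0.848 ± 0.280 in memory Tregs, and that at chromosome 9, 78504368 to 78507859, from 2.43 ± 0.172 to 0.735 ± 0.171. The region at chromosome 6, 80246501 to 80247657, fell from 3.70 ± 0.293 to 1.60 ± 0.265. Each of these 6 regions changed the same way in 3 of 3 donors, as the naming rule required. Adjusted p lay between 0.00532 and 0.0343 by limma.

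In total 11 regions were higher and 3 lower in memory than in naive Tregs, all of them in the same direction in 3 of 3 donors. With donor as a block the counts were 249 higher and 237 lower, with median log2 changes of 0.89 and −0.86, and 247 and 233 of them changed the same way in every donor. The paired fit added, among the largest changes, chromosome 9, 37408735 to 37409931 (log2 change 2.29, SE 0.289), chromosome 1, 159046369 to 159047559 (2.17, SE 0.263) and, lower in memory Tregs, chromosome 21, 15588077 to 15589263 (−1.77, SE 0.216). The paired counts were 139 and 109 without donor 1, 176 and 79 without donor 2, 183 and 392 without donor 3, 91 and 51 with summed windows, and 5 and 3 without centring. Without memory replicate 3 the unpaired fit called 0 regions in either direction, with 668 at an unadjusted p under 0.05. All log2 changes are relative to the library's median region. Without centring, the median log2 change over the tested regions was −0.22 for memory against naive, 0.52 for CD161+ against memory, and 0.29 for CD161+ against naive Tregs. The unpaired fit then called 0 regions in all 3 comparisons (46, 15 and 109 at an unadjusted p under 0.05).

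Calls differed in part between naive and memory libraries, although a missing call does not show that a region was closed. A total of 209 regions were called in 3 of 3 memory and 0 of 3 naive libraries, and 136 the other way. Their median normalized tag counts were 23.9 and 17.2, against 20.2 for all merged regions. These were averaged over all libraries that called a region, CD161+ libraries included. A stricter threshold, with each of the 3 calls above the library's median findPeaks score, left 24 and 3. Ranked by tag count relative to the median of the library's called regions, the first memory regions lay at chromosome 7, 126341005 to 126341658 (normalized tag count 68.3 ± 19.6), chromosome 10, 52267815 to 52268806 (51.6 ± 21.2) and chromosome 6, 106094080 to 106094876 (44.8 ± 11.02). Each was also called in 3 of 3 CD161+ libraries. On the naive side the first by the same ranking lay at chromosome 1, 213843436 to 213844248 (46.2 ± 26.8), chromosome 11, 66085142 to 66085917 (39.4 ± 27.2) and chromosome 2, 60114938 to 60115715 (35.6 ± 23.6). The memory share of these regions was 60.6% (95% interval 55.2 to 65.8), and it was 26.02%, 48.6% and 40.6% in regions called in 2 of 2 against 0 of 2 libraries without donor 1, 2 or 3. With equally long lists the share was 69.9% (65.1 to 74.4) over all donors, and 74.0%, 79.3% and 41.9% without donor 1, 2 or 3. The direction of this imbalance changed with the list length and with the donors included.

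CD161+ Tregs were compared with memory Tregs to ask what goes with CD161. Without a donor term, limma called 0 regions in either direction (243 at an unadjusted p under 0.05). With donor as a block 12 regions were higher and 12 lower in CD161+ Tregs, all in the same direction in 3 of 3 donors (852 at an unadjusted p under 0.05). The largest rise was at chromosome 6, 129601649 to 129602555, with a relative tag count of 1.79 ± 0.405 in CD161+ against 0.503 ± 0.127 in memory and 0.356 ± 0.0974 in naive Tregs (log2 change against memory 1.84, SE 0.242, adjusted p = 0.000507 in the paired fit). Next came chromosome 8, 17554718 to 17555511, with 1.68 ± 0.816 against 0.747 ± 0.386, and chromosome 12, 107421302 to 107421952, with 2.57 ± 0.402 against 1.15 ± 0.165. Naive Tregs had 1.24 ± 0.816 and 0.443 ± 0.141 at these regions, so at chromosome 8 memory Tregs had the lowest mean.

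Among regions lower in CD161+ than in memory Tregs in the paired fit, chromosome 9, 104332190 to 104333150, had a relative tag count of 0.366 ± 0.117 against 1.04 ± 0.379 (log2 change −1.48, SE 0.268, adjusted p = 0.00947). The region at chromosome 10, 24910864 to 24912460, had 0.590 ± 0.264 against 1.57 ± 0.386, and chromosome 2, 214097574 to 214098495, 0.410 ± 0.0583 against 1.06 ± 0.272. Leaving out CD161+ replicate 2 left 2 higher and 1 lower region in this fit. Summed windows left 0 (643 at an unadjusted p under 0.05), and no centring left 1 higher and 0 lower (970).

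**Figure D2:**
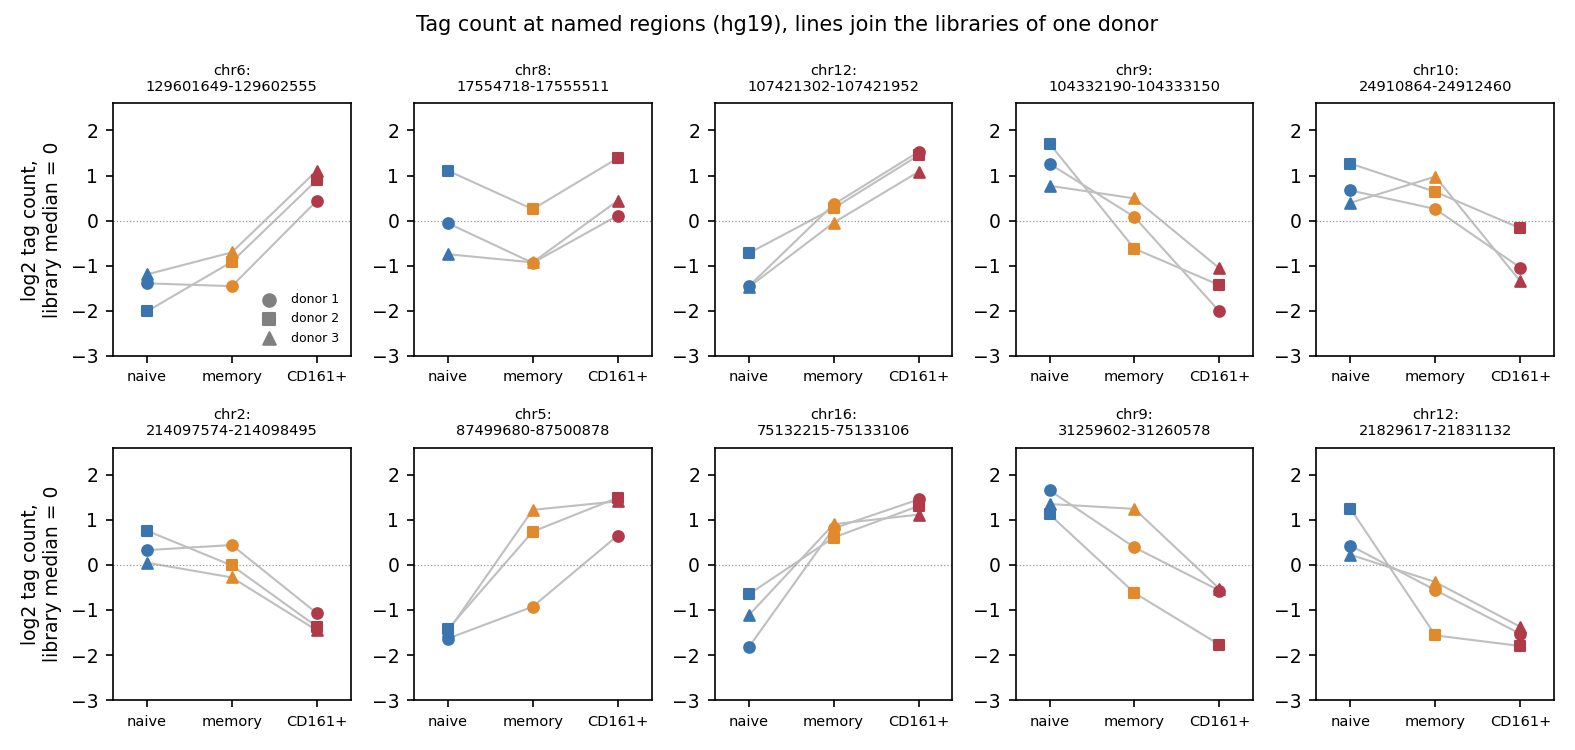
Log2 tag count, with the library's median region at 0, at 10 named regions in naive, memory and CD161+ Tregs, where points are libraries and lines join the 3 libraries of a donor. At chromosome 12, 107421302, the relative tag count was 0.443 ± 0.141 in naive, 1.15 ± 0.165 in memory and 2.57 ± 0.402 in CD161+ Tregs.

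By presence and absence, 236 regions were called in 3 of 3 libraries of one of these populations and 0 of 3 of the other. Of these, 20 were memory regions, a CD161+ share of 91.5% (95% interval 87.2 to 94.7). The median normalized tag count, averaged over the libraries that called a region, was 17.4 for the CD161+ and 19.3 for the memory regions, against 20.2 for all merged regions, and the stricter threshold left 4 CD161+ and 0 memory regions. With equally long lists the counts were 130 and 49, a share of 72.6% (65.5 to 79.0). Without donor 2 the share was 67.3% (63.3 to 71.2) with the lists as deposited, and 50.5% (46.4 to 54.7) with equally long lists, where 290 regions were called in 2 of 2 CD161+ and 0 of 2 memory libraries and 284 the other way. Ranked by tag count relative to the median of the library's called regions, the first CD161+ regions were at chromosome 4, 26132440 to 26133230 (normalized tag count 45.2 ± 21.9), chromosome 8, 10924328 to 10925035 (41.7 ± 16.0) and chromosome 12, 96199479 to 96200273 (38.7 ± 29.2). The first memory regions by the same ranking were at chromosome 5, 74407341 to 74408214 (32.2 ± 24.6), chromosome 10, 21344063 to 21344871 (28.9 ± 12.4) and chromosome 3, 124358518 to 124359390 (31.6 ± 28.5).

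CD161+ and naive Tregs differed at more regions. The largest rises were at chromosome 5, 87499680 to 87500878 (6.48-fold, from 0.351 ± 0.0258 to 2.34 ± 0.675), chromosome 12, 107421302 to 107421952 (5.94-fold) and chromosome 16, 75132215 to 75133106 (5.63-fold, from 0.459 ± 0.177 to 2.46 ± 0.284). The largest falls were at chromosome 9, 104332190 to 104333150 (from 2.46 ± 0.780 to 0.366 ± 0.117), chromosome 9, 31259602 to 31260578 (from 2.62 ± 0.490 to 0.553 ± 0.225) and chromosome 12, 21829617 to 21831132 (from 1.63 ± 0.651 to 0.340 ± 0.0497). Adjusted p in limma lay between 0.000228 and 0.00993 for these 6 regions. Each changed the same way in 3 of 3 donors, as the naming rule required. Memory Tregs had mean values between those of the other populations at all 6, an order that picking the largest differences between the other populations favours.

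In total 70 regions were higher and 73 lower in CD161+ than in naive Tregs, with median log2 changes of 1.30 and −1.39 and the same direction in 3 of 3 donors for each. With donor as a block there were 609 higher and 469 lower regions, with medians of 0.77 and −0.90. Without donor 1 the unpaired fit called 11 higher and 3 lower regions, without donor 2 it called 26 and 5, and without donor 3 it called 11 and 8. With the block the counts were 200 and 212 without donor 1, 292 and 220 without donor 2, 740 and 584 without donor 3, 189 and 109 with summed windows, and 44 and 6 without centring.

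Presence and absence gave 558 regions called in 3 of 3 CD161+ and 0 of 3 naive libraries and 211 the other way, a CD161+ share of 72.6% (69.3 to 75.7). Their median normalized tag counts, averaged over all libraries that called a region, memory libraries included, were 22.4 and 19.0. The stricter threshold left 78 and 16. Ranked by tag count relative to the median of the library's called regions, the first regions on the CD161+ side were at chromosome 7, 126341005 to 126341658 (normalized tag count 99.1 ± 64.7), chromosome 7, 106244894 to 106245702 (95.6 ± 56.8) and chromosome 1, 87869763 to 87870549 (92.4 ± 41.3). On the naive side the first by the same ranking were at chromosome 11, 123551650 to 123552328 (78.8 ± 48.6), chromosome 2, 205940668 to 205942491 (59.6 ± 25.7) and chromosome 18, 68376611 to 68377706 (61.2 ± 51.5). The CD161+ share was 54.0% (51.4 to 56.6) without donor 2. With equally long lists it was 78.3% over all donors, and 76.8%, 78.2% (75.9 to 80.4) and 58.9% without donor 1, 2 or 3.

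Across the 3 populations, 78 regions differed in tag count by the limma F test, and 853 with donor as a block. Donor itself went with more regions, 2755, when population was in the model. Leaving out donor 1, 2 or 3 lowered the count without a block to 14, 23 or 1, and no centring lowered it to 0. Of 100 drawn splits of the libraries, the real one included, 5 gave at least 78 regions without a block. With the block, leaving out donor 1, 2 or 3 gave 388, 442 or 1098, and all libraries gave 226 with summed windows and 35 without centring.

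On average over the 3 populations, libraries of one population from different donors shared more regions than libraries of different populations from different donors. The mean Jaccard index was 0.632 against 0.606, a difference of 0.0258 (exact permutation within donors, one-sided, p = 0.0278, the smallest that 36 arrangements can give). It was 0.0331 with equally long lists, at the same p. Between populations, memory and CD161+ Tregs of different donors had a mean index of 0.626, naive and CD161+ Tregs 0.604, and naive and memory Tregs 0.589. With equally long lists these were 0.734, 0.682 and 0.696. Within populations the means were 0.665 for CD161+, 0.619 for naive and 0.614 for memory Tregs, or 0.754, 0.726 and 0.732 with equally long lists. Libraries of different populations from the same donor had an index of 0.682, or 0.739 with equally long lists.

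**Figure D3:**
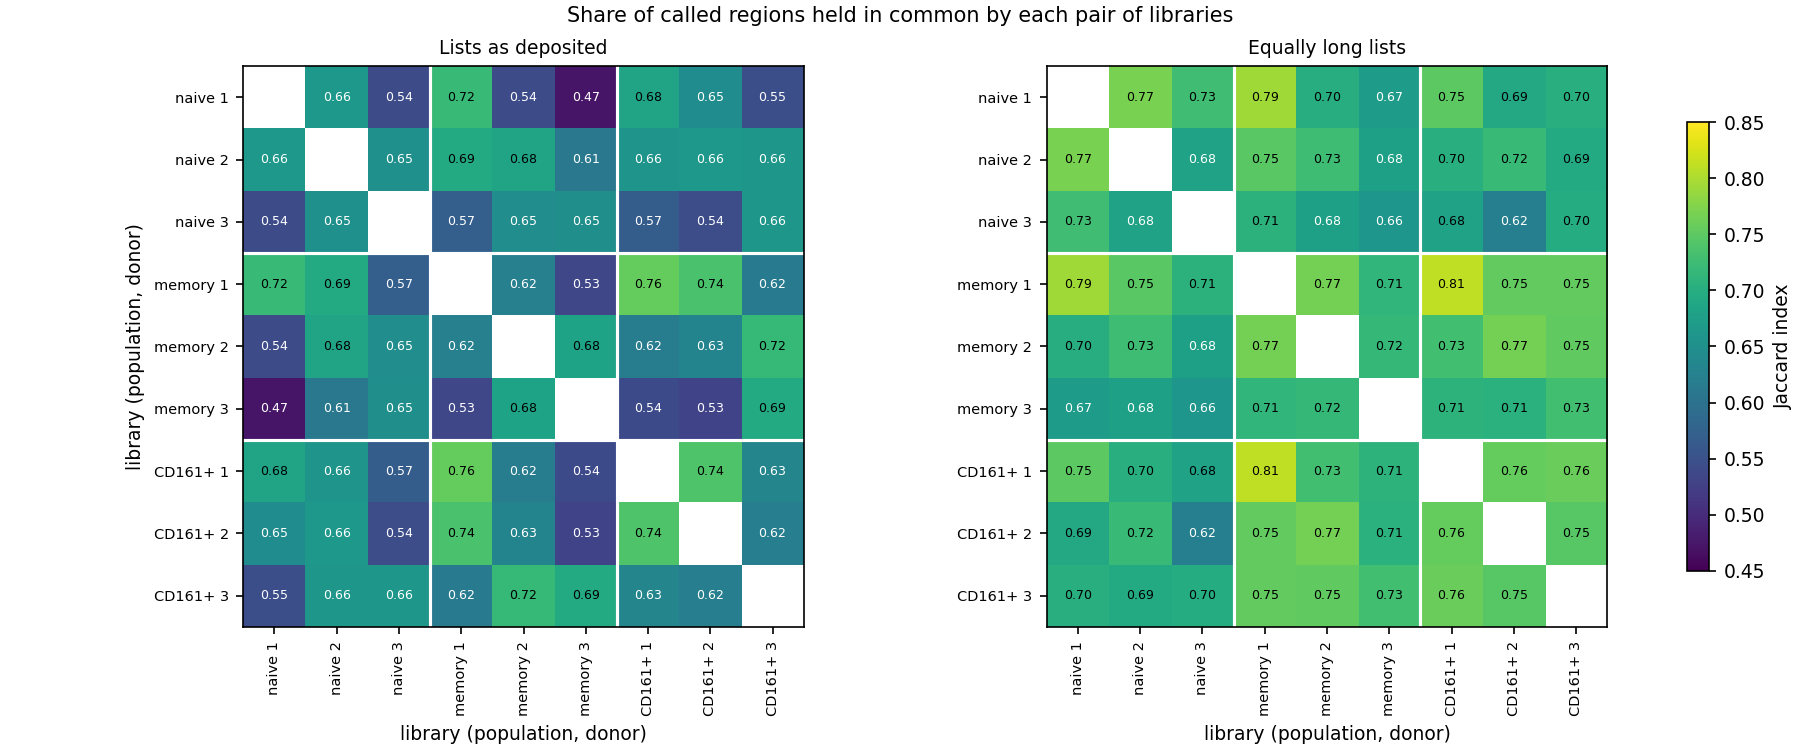
Jaccard index of called regions for each pair of the 9 libraries, with the lists as deposited on the left and the 35090 windows of each library with the highest findPeaks scores on the right. Rows and columns are libraries by population and donor, and white lines part the populations. The mean over same-population pairs of different donors was 0.632 on the left and 0.737 on the right.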

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

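Mitochondrial windows were left out of every comparison, and they held a large part of the tags in each library. At least 25.8% ± 4.55 (SD, n = 3) of all tags fell in mitochondrial windows in naive, 31.4% ± 14.4 in memory and 33.2% ± 3.89 in CD161+ libraries. They stand out as a signal in data that no comparison used. The joint test of the 3 populations gave p = 0.639 (exact permutation within donors, two-sided). CD161+ libraries nevertheless had a higher share than naive libraries in each donor, with 32.7% against 21.4%, 37.3% against 30.5% and 29.6% against 25.6%. The shares ranged from 16.5% to 45.2% over the libraries, both of these in memory Tregs. With 3 libraries per population, no test for single outlying libraries was run.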

How the results depend on the processing

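Alternatives within the donor block, those that combine equally long lists with a left-out donor, those for regions called in one population alone, and those for regions called in 6 of 6 libraries of 2 populations and 0 of 3 of the other were added after the data were examined, and the rest were set beforehand. The cause of each change was not tested unless stated. For called regions per library, exact permutation within donors gave p = 0.306 over the 3 populations, and 0.472 with a stricter threshold. Without a donor it gave 0.167 to 0.667, where 6 arrangements cannot go under 0.167. The Jaccard difference of 0.0258 stayed above 0 in every setting, at 0.0176 to 0.0327 without a donor, with a p of 0.167 that 6 arrangements cannot pass.

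For regions called in 3 of 3 against 0 of 3, merging rules moved no count by over 1.5 times. A stricter threshold left 24 higher and 3 lower for memory against naive, 4 and 0 for CD161+ against memory, and 78 and 16 for CD161+ against naive, since fewer calls qualify. Equally long lists gave 130 and 49 for CD161+ against memory. Without a donor, when 2 of 2 against 0 of 2 is easier to meet, counts rose to 422 to 629 higher and 490 to 1200 lower for memory against naive, 381 to 1628 and 52 to 185 for CD161+ against memory, and 783 to 1916 and 416 to 1020 for CD161+ against naive. Regions called in one population alone numbered 537 to 1251, and those called in 6 of 6 libraries of 2 populations and 0 of 3 of the other, 151 at first, numbered 330 to 672.

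For changed tag counts without a block, the replicate block gave 249 higher and 237 lower regions for memory against naive, 12 and 12 for CD161+ against memory, and 609 and 469 for CD161+ against naive, in place of 11 and 3, 0 and 0, and 70 and 73. No centring gave 0 for each. Memory against naive gave 138 and 40 with the floor for uncalled values, which tests more regions (27480), 22 higher with summed windows, 7 and 5 in the 6 libraries alone, and 7 and 6 lower with quantile normalization and with the filter on low values. CD161+ against naive gave 394 and 357 with the floor, 43 and 20 with summed windows, and 45 higher in the 6 libraries alone. CD161+ against memory gave 0 under each alternative without the block (limma), with 15 to 897 regions at an unadjusted p under 0.05 among the settings that kept all libraries. The three-group count of 78 was 0 without centring and 853 with the replicate block.

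Within the replicate block, no centring left 5 and 3 for memory against naive, 1 and 0 for CD161+ against memory, and 44 and 6 for CD161+ against naive. The floor gave 768 and 524, 58 and 65, and 1543 and 1619. Summed windows gave 91 and 51, 0 and 0 (643 at an unadjusted p under 0.05), and 189 and 109. The 6 libraries alone gave 161 higher for memory against naive. The low-value filter gave 8 and 9 for CD161+ against memory, and quantile normalization 9 and 8.

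Leaving out a donor or a library moved most counts. Without the block, memory against naive ranged from 0 to 50 higher and 0 to 14 lower, CD161+ against naive from 11 to 73 and 3 to 94, and CD161+ against memory was 0 throughout (147 to 409 at an unadjusted p under 0.05); the three-group count ranged from 1 to 23 without a donor. Within the block the ranges were 128 to 240 and 79 to 392, 200 to 984 and 212 to 650, and 2 to 20 and 1 to 33 for CD161+ against memory. Memory against naive gave 50 higher without naive replicate 2, 0 without memory replicate 3, 3 without memory replicate 2, 4 without naive replicate 1 and 7 without CD161+ replicate 3. Lower regions numbered 14 without naive replicate 3, 7 without memory replicate 1, 6 without naive replicate 2, 5 without CD161+ replicate 1, and 0 without naive replicate 1, memory replicate 2 or memory replicate 3. CD161+ against naive gave 18 and 13 without naive replicate 1, 19 and 32 without CD161+ replicate 2, 28 and 21 without CD161+ replicate 3, 36 higher without CD161+ replicate 1 and 23 lower without naive replicate 2.

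In the paired fit, memory against naive gave 135 and 125 without naive replicate 1, 164 and 85 without naive replicate 2, 147 higher without naive replicate 3, 164 and 128 without memory replicate 1, 138 lower without memory replicate 2 and 128 higher without memory replicate 3. CD161+ against naive gave 311 and 238 without naive replicate 1, 230 lower without naive replicate 2, 366 higher without naive replicate 3, 984 higher without memory replicate 3, 243 and 267 without CD161+ replicate 1 and 237 and 247 without CD161+ replicate 2. CD161+ against memory gave 3 and 4 without memory replicate 1, 33 lower without memory replicate 2, 2 lower without memory replicate 3, 3 higher without CD161+ replicate 1, 2 and 1 without CD161+ replicate 2 and 3 and 1 without CD161+ replicate 3.

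Of 570 alternatives for the 30 changes named from the 2 fits, 496 kept their direction and side of the threshold, 74 kept the direction and lost the threshold, and 0 reversed. The largest losses came in the fit without the block. There, no centring took all 12 changes named from that fit below the threshold, and leaving out donor 3 took 8 of them. Regions named in both fits count in each, and all were picked for large changes in the same direction in every donor, which favours these numbers. Comparisons of gene lists, of positions relative to genes and of sequence motifs were not run, so their alternatives were not run either. Whether depth limits the lists was not tested: the deepest library, memory replicate 2, with 16179000 tags, called 19260 regions, and CD161+ replicate 2, with 11253201 tags, called 28112.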

Other observations

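The tests of loci, of held-out donors, of regions called in one population alone, of the memory library of donor 2, and of equally long lists without a donor were chosen after the main results were seen. Regions lower in CD161+ than in naive Tregs lay close together more often than shuffled labels gave. In the fit with donor as a block, 38 of the 469 lower regions formed 12 loci of at least 3 regions spaced within 100 kb, against a mean of 1.02 loci and at most 5 in 1000 shuffles of the labels over the tested regions (permutation p = 0.001, the smallest these can give). At chromosome 18, 68326159 to 68449839, 4 of 4 tested regions were lower, with a median log2 change of −1.07. At chromosome 4, 108950273 to 108994171, and chromosome 12, 92753954 to 92798286, 3 of 3 were lower, with medians of −1.40 and −1.20. The 609 regions higher in CD161+ Tregs formed 3 loci, against a mean of 2.08 (permutation p = 0.341), of which chromosome 16, 75108786 to 75146142, had a median of 1.23. Memory against naive Tregs gave 3 loci of lower regions (permutation p = 0.001) and 2 of higher ones (permutation p = 0.012). These shuffles treat regions as independent, so they account neither for neighbouring regions that vary together nor for the spread over donors.

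Changes found in 2 donors recurred in the third. Regions at least 1 higher on the log2 scale in memory than in naive Tregs in 2 donors were higher by 1.10 ± 0.33 (SD over the 3 held-out donors) in the third, and regions lower by as much were at −0.94 ± 0.29. At these same regions CD161+ minus naive was 1.15 ± 0.25 and −1.01 ± 0.13. Regions chosen on CD161+ against naive Tregs gave 1.01 ± 0.13 and −1.12 ± 0.27, with memory minus naive at 0.84 ± 0.06 and −0.72 ± 0.40. CD161+ minus memory was 0.25 ± 0.17 and −0.39 ± 0.12 there, in the chosen direction in 3 of 3 donors, although the same regions had been chosen on CD161+ values of other donors. Regions chosen on CD161+ against memory Tregs were few (5 to 11 per donor) and gave 1.00 ± 0.05 and −0.48 ± 0.08.

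Of the 209 regions called in 3 of 3 memory and 0 of 3 naive libraries, 136 were called in 3 of 3 CD161+ libraries and 3 in 0. A total of 120 regions were called in 3 of 3 CD161+ and 0 of 6 other libraries, 62 in naive and 3 in memory libraries alone, or 80, 61 and 10 with equally long lists. Without donor 2, where 2 of 2 against 0 of 4 libraries is easier to meet, these were 199, 272 and 66, so naive Tregs then had the most such regions. Leaving out donor 1 gave 699, 308 and 16, and leaving out donor 3 gave 738, 483 and 30, so CD161+ Tregs kept the most there. Of the 36 arrangements of the populations within donors, 1, the real one, gave as many as 185 such regions. The highest other gave 136, with naive and memory exchanged in donor 2. A share of 1 in 36 is the smallest these arrangements can give, in a test chosen after the main results were seen. It argues only weakly against chance arrangement of the labels.

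More regions were called in 3 of 3 CD161+ and 0 of 3 memory libraries than the reverse. The CD161+ share with equally long lists was 72.6% (95% interval 65.5 to 79.0). This argues against shorter memory lists, counted in windows, as the only cause. Those lists were equal in windows and can still differ in regions, so list length in regions was not tested. A share of 90.7% without donor 3 argues against its weak memory library alone. The weak memory library of donor 2 stayed in there. Leaving out donor 2 lowered the share from 91.5% to 67.3%, so that donor went with a part of the imbalance but not all of it. The intervals treat regions as independent. Both together, equal lists and no donor 2, gave 50.5% (46.4 to 54.7), an interval that holds 50%, whereas leaving out donor 1 or 3 gave 67.4% and 76.1%. The imbalance may thus come from list length and the memory library of donor 2 together, in which at least 8.89% of non-mitochondrial tags lay in called windows against 33.2% in its CD161+ partner (7.42% and 20.8% of all tags). A difference between the populations in donor 2 stays open and was not tested.

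Libraries of different populations shared more regions within a donor than between donors. The difference of the mean Jaccard index was 0.0759, and 0.0347 with equally long lists, or 45.8% of it. Without donor 1, 2 or 3 it was 0.0452, 0.142 or 0.0408 with the lists as deposited. This lies between the bounds set beforehand, under 25% for list length and enrichment as the cause and at least 75% for neither. Donor biology and the quality of the libraries prepared from a donor cannot be told apart here, because each donor gave 1 library per population.

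CD161+ Tregs were not shown to lie farther from naive Tregs than memory Tregs did, at regions chosen on memory against naive Tregs. The difference along the memory change was 0.0428 ± 0.0746 on the log2 scale (mean and SD over 3 held-out donors). It was 0.0628 in donor 1, whose memory library had the higher share of tags in called windows, which meets the bound set against lower signal to noise in memory libraries but lies within the spread. It was −0.0397 in donor 2, where the memory library had the lowest share against its CD161+ partner, and 0.105 in donor 3. For regions lower in memory Tregs the median followed the memory change in 1 of 3 donors, which meets the bound set against a further step in CD161+ Tregs, but CD161+ minus memory there, at −0.05 ± 0.29, too lies within the spread. Neither explanation can be decided from 3 donors. Choosing regions on memory against naive Tregs also favours a large memory change, which leans towards a small difference. Regions chosen on CD161+ against naive Tregs gave CD161+ minus memory at 0.25 ± 0.17 and −0.39 ± 0.12, a choice that leans the other way.

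Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For changed tag counts, 1 of 10 splits gave as many as the real 14 for memory against naive (highest other 0), 1 of 10 as many as 143 for CD161+ against naive (highest other 0), and 10 of 10 as many as 0 for CD161+ against memory (highest other 7). For regions called in 3 of 3 against 0 of 3, 4 of 10 gave as many as 345 for memory against naive (highest other 1941), 3 of 10 as many as 236 for CD161+ against memory (highest other 2629) and 2 of 10 as many as 769 for CD161+ against naive (highest other 1389). Splits that call several times the real number point to structure among the donors and libraries. Among the 4 splits that part all 3 donor pairs, as the real one does, the highest other gave 48, 108 and 79.

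For the F test over 3 populations, 5 of 100 drawn splits gave at least 78 regions, so these splits could not exclude chance without the block. They do not keep the libraries paired by donor, so differences between donors enter the counts. The highest other, 522, equals the count when the libraries are split by donor. With donor as a block, 1 of the 36 arrangements within donors gave 853. The highest other gave 852, with memory and CD161+ Tregs exchanged in donor 3, and exchanging them in donor 2 or in both gave 574 and 513. Every arrangement that moved a naive library gave at most 8, so the count separated naive Tregs from the others and said little about memory against CD161+ Tregs.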
